A study of Arabidopsis thaliana with 24 samples.

How the data were processed

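The series measured messenger RNA in rosettes of Arabidopsis thaliana Col-0 on 24 one-colour oligonucleotide arrays, 2 for each of 6 temperatures (20, 17, 14, 12, 10 and 8 °C) at each of 2 harvest times (6 h and 78 h). Per the labels' protocols, total RNA was extracted with Trizol and about 10 µg was made into biotin-labelled cRNA. The labels state 130 µmol of light and 3 rosettes per sample. The values deposited by the authors are on the log2 scale, at least by their range, since the base is not stated and was inferred from a top value of 14.81, under the log2 of a 16-bit scanner limit. The deposited values had been normalized between arrays. The sorted values of each array lay within 0.116 of the mean sorted profile, and the array medians were between 7.151 and 7.251. The method of normalization, the background correction and the software are not given in the sources used here. The deposited normalization was kept.

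The table held 22810 probe sets. The 64 control probe sets were left out of the tests, and 22746 were tested. Genes were taken from the given probe set annotation. It listed 1 gene for 13513 probe sets (59.4%), several for 503 and none for 8730. The 13513 named 13350 genes, 13436 of these probe sets matched the TAIR10.1 gene table and 77 did not, and for 11933 the locus code was the only name. No gene was named from a probe set with several genes, and unlisted probe sets are unnamed here, not without a gene. CBF1, CBF2, CBF3, COR78, GOLS3, CHS and RBCS1A, which were to be reported always, were on no listed probe set and were not analysed here.

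A linear model with 1 mean per group was fitted to all 24 arrays in limma 3.58.1 (R 4.3.3) with empirical Bayes moderation and 12 residual degrees of freedom. Slopes are linear contrasts over the 6 group means, in log2 change per 10 °C of cooling. Curvature is the quadratic contrast orthogonal to it. Each lower temperature was compared with 20 °C at the same time, and these comparisons share control arrays within a time. The 20 °C plants of 78 h were compared with those of 6 h as the background. Probe sets were called at a Benjamini-Hochberg adjusted p below 0.05 over all 22746, and all adjusted p-values are from limma. Fold changes are 2 to the power of the log2 value.

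Gene lists were tested with camera of limma on both slopes and on their difference, with a preset correlation of 0.01 between genes, adjusted over lists and the 3 contrasts, separately for the first and the added lists, for lists with at least 3 measured members. A gene with several probe sets was represented by the brightest. Of 37 lists with 588 entries, 98 entries were named on the arrays. Such entries are called measured members here, and the others may lie on unnamed probe sets. This left 17 lists for the test, 13 with 1 or 2 members and 7 with none. The lists with no members covered abscisic acid, glycine-rich RNA-binding proteins, galactinol and raffinose synthesis, fatty acid desaturation, nitrogen metabolism, and flower and seed markers, and were not analysed here. Another 19 lists were written from the annotation table, before any of their values was tested, and are given among the other observations, except for 1 that is not reported here.

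The named genes are, per main comparison, the 12 rising and the 8 falling probe sets with a single gene and the largest estimates among those past the test, per temperature the 2 largest each way, and from each list up to 4 members with the largest slopes. UGT78D1, UGT78D2 and AT5G53920 lie outside this rule and were named after their values were seen, as were members of the added lists.

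Whether the letters A and B pair the arrays was checked on the differences between the A and the B array of each group. Across all 66 pairs of groups these differences correlated between 0.52 and 0.89 across probe sets (median 0.67, with 0.77 within a harvest time and 0.63 between times). The letter was therefore also fitted as a block, with 11 residual degrees of freedom. The median standard error of a slope was 0.098 without and 0.069 with it. Since both letters are present in every group, the slope estimates are the same in both fits. The other alternatives were median centring, cyclic loess, leaving out the dimmest 25% of probe sets, empirical Bayes with trend and robust estimation, array weights, each harvest time alone, regression on temperature, leaving out each array, camera with an estimated correlation, and the mean of a gene's probe sets. After the data were seen, the A arrays alone, the B arrays alone, the block with each harvest time alone, and the block with an estimated correlation were added. Each letter alone was fitted as a straight line on temperature at each time, with 1 array per temperature. Its p-values measure scatter around that line and not the spread between samples.

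The pipeline was tested on simulated data with 22746 probe sets, of which 200 changed. Without the block, slopes at 6 h of 0.3, 0.6 and 1.2 were recovered in 20.9%, 70.1% and 92.4% of cases, and with it in 47.8%, 95.5% and 100%. At 78 h these were 14.9%, 67.2% and 89.4% without and 43.3%, 91.0% and 100% with the block, and for the difference 10.4%, 35.8% and 84.8% without and 17.9%, 74.6% and 97.0% with it. Of 22546 unchanged probe sets at most 2 were called without the block and at most 11 with it. The 11 stood beside 12, 50 and 64 changed probe sets called for differences of 0.3, 0.6 and 1.2. The simulated letter difference of a probe set was the same in all groups, as the block assumes. In the data these differences correlated less between harvest times than within them. The values with the block therefore hold for that assumption only. Camera called a simulated list of 13 shifted by 0.4 (adjusted p = 2.54e-66) and 0 of 100 unshifted lists. The simulated noise was independent between probe sets and list members were drawn at random. This therefore does not test camera on lists whose genes vary together. To test for chance, the temperature labels were redrawn within each letter and harvest time, or the harvest times exchanged within pairs of arrays of a temperature and letter, giving 100 assignments with the real one.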

Results

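Rosettes of Arabidopsis thaliana, accession Col-0, were grown on soil at 20 °C for 4 weeks in 12 h of light per day and moved, 4 h into the light, to 20, 17, 14, 12, 10 or 8 °C. Plants kept at 20 °C served as the control. Rosettes were frozen 6 h or 78 h after the move, in both cases 10 h into the light, so that the harvests fell at the same time of day. Each sample held 3 rosettes. Each of the 12 combinations of temperature and time was measured on 2 one-colour oligonucleotide arrays, which the labels mark A and B. The 24 arrays carried 22746 probe sets for plant transcripts. The deposited signals lay between 3.87 and 14.81 on the log2 scale and array medians between 7.15 and 7.25. A single gene was listed for 13513 of these probe sets, several genes for 503 and none for 8730, which are unnamed here. The labels' treatment protocol mentions typically at least 5 replicate samples, while each group has 2 arrays. How the 2 relate to those samples was not settled here. The labels do not state where the replicates come from beyond separate samples of 3 rosettes. The p-values of the main fit therefore measure the spread between these samples, and the number of arrays limits the precision of all values.

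The letters A and B were the largest source of variation among the arrays. The first principal component, with 39.2% of the variance, placed all A arrays on one side and all B arrays on the other. Component 2 (23.4%) ran from warm to cold, and component 3 (13.5%) set the 78 h arrays of 12, 10 and 8 °C apart from the 6 h arrays. The A and B array of a group correlated between 0.982 and 0.992 across probe sets. At 13686 probe sets (60.2%) the letters differed in limma. Differences between the letters enter the error of the tests below. Counts are therefore also given with the letter as a block where they differ. Each group holds 1 array of each letter, so the block leaves slope estimates unchanged and alters their error alone. Calls kept with it are thus no separate support. Fits without 1 array had no block, so the group left with 1 array carries the letter difference in its mean. Called gene list shifts are also given for the A and the B arrays alone, each fitted as a straight line on temperature. Their p-values measure scatter around that line.

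**Figure D1:**
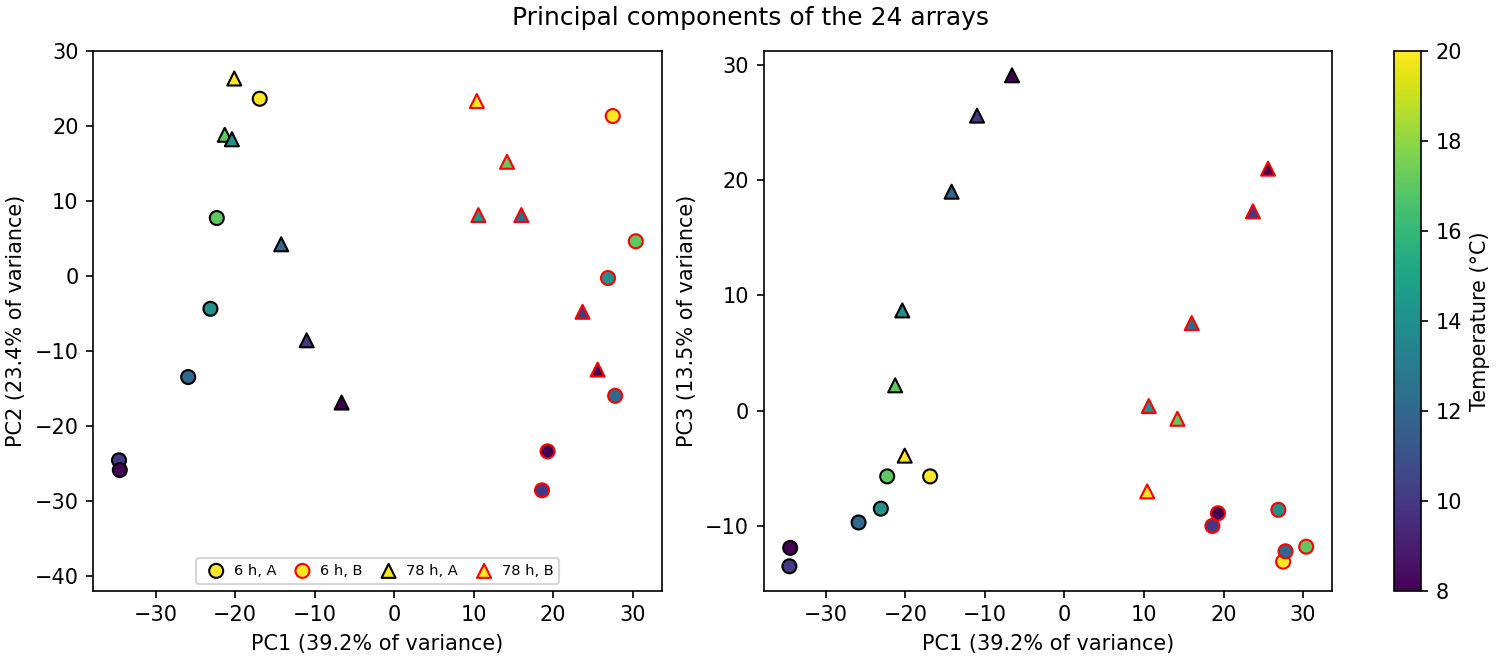
Each point is 1 of the 24 arrays on the first principal component (x axis) and on component 2 or 3 (y axes), coloured by temperature, with circles for 6 h and triangles for 78 h and with black outlines for A and red outlines for B. The A arrays lie left of 0 and the B arrays right of 0 on the first component, which holds 39.2% of the variance.

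The first question was which transcripts followed temperature 6 h after the move. The dehydrin LTI30 rose most among the probe sets with a single gene, by 3.81 ± 0.36 log2 per 10 °C of cooling (limma adjusted p = 1.15e-05), or 14.0-fold. Its mean went from 9.18 at 20 °C to 13.57 at 8 °C (SD 0.58 and 0.31, n = 2). Slopes rest on the 12 arrays of a time, and their SE on the spread shared by all 24 arrays. The dehydrin COR47 rose by 2.44 ± 0.53 (adjusted p = 0.0079), and the zinc finger repressor STZ, also called ZAT10, by 2.31 ± 0.45 (adjusted p = 0.00371). AT1G51090 rose by 2.89 ± 0.45 and AT1G32860 by 2.82 ± 0.26. AT2G16890, which encodes a UDP-glycosyltransferase, rose by 2.58 ± 0.11, and AT1G48100, AT1G73480, AT3G17130, AT1G16850, AT4G36010 and AT5G62360 by up to 2.55. The strongest fall was that of AT2G34620, at -2.33 ± 0.09 (adjusted p = 2.88e-09), which went from 9.92 at 20 °C to 7.36 at 8 °C. AT4G33660 fell by 1.77, AT3G47560 fell by 1.72, AT3G26510 fell by 1.64 and AT4G33666 fell by 1.57 log2 per 10 °C. Then came AT2G03750 at -1.55, AT1G23390 at -1.53 and AT1G19000 at -1.50. In all, 2513 of 22746 probe sets had a slope at 6 h (1114 rising and 1399 falling with cooling). With the replicate letter as a block the number was 6131 (2780 rising and 3351 falling), and all 2513 were among them. Without the block and with the 6 h arrays fitted alone it was 1458. Over all probe sets the slopes in the A arrays and in the B arrays correlated at 0.76. Without the B array of 20 °C at 6 h the number was 1473. The calls of COR47 and AT5G62360 were each lost without at least 1 array, with adjusted p up to 0.0749 and 0.181.

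Of the gene lists fixed before the data were examined, the COR genes and dehydrins, induced by cold in the CBF pathway, rose at 6 h. Of the list's 15 genes 4 were on probe sets with a named gene, and counts of list members cover such genes alone. All 4 passed the test, over all probe sets as well as adjusted over the list alone. Beside LTI30 and COR47 these were COR15B, at 0.82 ± 0.14, and COR15A, a chloroplast protein that protects membranes in freezing, at 0.63 ± 0.09 log2 per 10 °C, with mean signals of 13.46 and 13.95 near the top of the range. The list's median slope was 1.63 (limma camera adjusted p = 1.13e-05; adjusted p = 0.106 with an estimated correlation). It was 1.41 in the A arrays and 1.85 in the B arrays. Ribosome biogenesis genes rose as a list of 13 with a median of 0.39 (adjusted p = 0.00169; adjusted p = 0.392 with an estimated correlation; medians 0.21 in A, where adjusted p = 0.0883, and 0.42 in B). Without the A array of 20 °C at 6 h the median was 0.175 (adjusted p still under 0.05). The nucleolar genes YAO and PRH75 rose by 0.65 ± 0.10 and 0.65 ± 0.11. AT3G15460 had a slope of 0.43 ± 0.14 that passed only with the block (3 of 13 past the test, 4 adjusted over the list alone and 7 with the letter as a block). The gibberellin receptors GID1A, GID1B and GID1C had a median of 0.27 (adjusted p = 0.0475; adjusted p = 0.207 with an estimated correlation; 0.22 in A and 0.32 in B). GID1B, at 0.92 ± 0.26, and GID1C, at 0.27 ± 0.07, were past the test and GID1A, at 0.21 ± 0.17, past it only with the block. Without 1 array the adjusted p of GID1B and GID1C reached 0.188 and 0.153.

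Photorespiration genes fell at 6 h. Hydroxypyruvate reductase, HPR, had a slope of -0.51 ± 0.08 and the glycine decarboxylase T protein, AT1G11860, one of -0.39 ± 0.09. Glycerate kinase, AT1G80380, at -0.10 ± 0.06, did not pass. The median was -0.39 (adjusted p = 0.00847; adjusted p = 0.106 with an estimated correlation; -0.40 in A, where adjusted p = 0.0883, and -0.19 in B). The 3 measured members of the sugar-starvation list, MCCA, MCCB and IVD, all belong to leucine breakdown. MCCA fell by 0.72 and MCCB fell by 0.49 log2 per 10 °C, and IVD had a slope of -0.05 ± 0.07. The list median was -0.49 (adjusted p = 0.0415; adjusted p = 0.122 with an estimated correlation; -0.51 in A, where adjusted p = 0.0851, and -0.47 in B). The call of AT1G11860 was lost in 1 and that of MCCB in 17 of the 24 omissions of 1 array (adjusted p up to 0.0648 and 0.286). Without the block no member passed, and no list shift was called at 6 h, among photosystem subunits (0 of 4, median 0.06, adjusted p = 0.524), cytosolic ribosomal proteins (0 of 4, -0.01, 0.946), light-harvesting proteins (0 of 3, 0.02, 0.895), Calvin cycle enzymes (0 of 3, -0.07, 0.854), chlorophyll synthesis (0 of 6, -0.11, 0.38), alternative respiration (0 of 3, 0.23, 0.367) and root markers (0 of 3, -0.01, 0.952). With the block 3 chlorophyll synthesis genes passed with falling slopes, 1 gene each way among light-harvesting proteins and in the Calvin cycle, and 1 rising gene of alternative respiration, and none of these lists was called. In reactive oxygen scavenging the glutathione reductase GR1 rose by 0.70 ± 0.09, 1 of 4 members, or 2 with the block, with a list median of 0.13 (adjusted p = 0.367). Among flavonoid genes 2 of 6 rose, UGT78D2 by 1.37 ± 0.15 and the anthocyanin malonyltransferase AT5MAT by 0.67 ± 0.16. The list as a whole did not pass (median 0.10, adjusted p = 0.113, and 0.0474 in the B arrays). AT5MAT and Fes1A lost their calls without at least 1 array (adjusted p up to 0.0938 and 0.176). Of 9 heat shock proteins and chaperones 2 rose, among them Fes1A by 0.47 ± 0.12, and 1 fell only adjusted over the list alone or with the block, with a list median of 0.09 (adjusted p = 0.739). Plastid ribosomal proteins had 1 of 5 members past the test (3 with the block), AT3G13120 at -0.29 ± 0.05. Their median was -0.17 (adjusted p = 0.0614, and 0.0401 with the block; adjusted p = 0.342 with both the block and an estimated correlation).

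The same question was asked 78 h after the move. LTI30 still led, with a rise of 2.77 ± 0.36 log2 per 10 °C (adjusted p = 0.000177, 6.83-fold), followed by the sucrose transporter SWEET13 with 2.55 ± 0.20 (adjusted p = 3.98e-06) and AT2G16890 with 2.51 ± 0.11. SWEET13 went from 6.67 at 20 °C to 9.74 at 8 °C (SD 0.23 and 0.38, n = 2). The vacuolar processing enzyme BETA-VPE rose by 2.13 ± 0.18. Genes of flavonoid synthesis were among the strongest, with the chalcone isomerase-like gene CHIL at 2.03 ± 0.47 (adjusted p = 0.011), dihydroflavonol reductase, DFR, at 1.72 ± 0.19 (adjusted p = 4.74e-05) and the anthocyanin glucosyltransferase AT4G14090 at 1.63 ± 0.33 (adjusted p = 0.0045). AT1G80130 rose by 2.44 ± 0.22 and AT5G62210 by 2.26 ± 0.42. AT1G48100, AT1G16850 and AT1G19450 rose by 1.89, 1.67 and 1.64. The steepest falls were those of AT3G56060, at -2.3 ± 0.37 (adjusted p = 0.000926), and the expansin EXPA8, a protein of wall loosening, at -2.16 ± 0.40 (adjusted p = 0.00277), which went from 9.51 to 6.98 (SD 0.81 and 0.35, n = 2). The drought-induced gene DI19 had a slope of -1.54 ± 0.07 (adjusted p = 4.57e-08). AT1G35710, AT1G22890, AT1G76960, AT2G32160 and AT1G25230 had slopes of -2.14, -1.97, -1.65, -1.62 and -1.55. At 78 h 2750 probe sets had a slope (1208 rising and 1542 falling), 6711 with the letter as a block (3279 rising and 3432 falling). All 2750 were among these, and the slopes in A and in B correlated at 0.82 over all probe sets. The number was 1460 without the A array of 20 °C at 78 h and 1708 without the A array of 8 °C at 78 h. The calls of CHIL, AT1G35710, AT1G22890 and AT1G76960 were each lost without at least 1 array (adjusted p up to 0.0756, 0.145, 0.156 and 0.177).

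At 78 h the flavonoid and anthocyanin list rose, with 5 of 6 members past the test both over all probe sets and adjusted over the list alone. Beside DFR and AT4G14090 these were AT5MAT at 1.53 ± 0.16, UGT78D2 at 1.4 ± 0.15 and the anthocyanin xylosyltransferase UF3GT at 1.4 ± 0.21. UGT78D1, at 0.28 ± 0.17, did not pass. The median was 1.47 (adjusted p = 4.91e-07; adjusted p = 0.106 with an estimated correlation; 1.45 in A and 1.53 in B). The 4 cytosolic ribosomal proteins rose by between 0.32 (AT5G02870) and 0.50 (AT3G09200), with a median of 0.44 (adjusted p = 0.000102; adjusted p = 0.142 with an estimated correlation; 0.45 in A and 0.44 in B). AT5G02870 lost its call in 14 of the 24 omissions of 1 array (adjusted p up to 0.269). Ribosome biogenesis genes had a median of 0.49 (adjusted p = 0.000785; adjusted p = 0.359 with an estimated correlation; 0.61 in A and 0.36 in B). YAO at 0.58 ± 0.10 and AT3G15460 at 0.57 ± 0.14 were past the test, 3 past it adjusted over the list alone and 10 of the 13 past it with the block. The COR genes and dehydrins had a median of 0.75 (adjusted p = 0.000304; adjusted p = 0.158 with an estimated correlation; 0.64 in A and 0.90 in B). COR15A and COR15B rose by 0.73 ± 0.09 and 0.77 ± 0.14. COR47, at 0.63 ± 0.53, passed only with the block (adjusted p = 0.00288). In the list of reactive oxygen scavenging the glutathione reductases GR1 and GR and the stromal ascorbate peroxidase SAPX rose by 1.38 ± 0.09, 0.38 ± 0.10 and 0.76 ± 0.07. The thylakoid ascorbate peroxidase TAPX had a slope of -0.54 ± 0.07 (median 0.57, adjusted p = 0.0187; adjusted p = 0.106 with an estimated correlation; 0.57 in A and 0.57 in B). AT3G15460 and GR lost their calls without at least 1 array (adjusted p up to 0.153 and 0.188).

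Photosystem subunits encoded in the nucleus fell at 78 h in 3 of 4 cases, PSAN by a slope of -0.35 ± 0.05, PSAE-1 by one of -0.32 ± 0.05 and PSBW by one of -0.32 ± 0.07. PSBY had one of -0.08 ± 0.05. The median was -0.32 (adjusted p = 0.000592; adjusted p = 0.0476 with an estimated correlation; adjusted p = 0.135 with both the block and an estimated correlation; -0.38 in A and -0.24 in B). Photorespiration fell, with HPR at -0.48 ± 0.08 and AT1G80380 at -0.41 ± 0.06 past the test and AT1G11860 at -0.16 ± 0.09 short of it (median -0.41, adjusted p = 0.00276; adjusted p = 0.106 with an estimated correlation; -0.49 in A, where adjusted p = 0.0921, and -0.31 in B). Of the leucine breakdown genes MCCA and IVD fell, at -0.56 ± 0.13 and -0.40 ± 0.07. MCCB had a slope of -0.13 ± 0.15 (median -0.40, adjusted p = 0.0187; adjusted p = 0.106 with an estimated correlation; -0.50 in A and -0.31 in B, where adjusted p = 0.111). The inner antenna proteins LHCB4.2 and LHCB4.1 fell, at -0.45 ± 0.12 and -0.19 ± 0.06. LHCB4.3 had a slope of -0.09 ± 0.21, and the light-harvesting list did not pass (median -0.19, adjusted p = 0.0783). The calls of PSBW, MCCA, LHCB4.2 and LHCB4.1 were each lost without at least 1 array (adjusted p up to 0.0758, 0.093, 0.172 and 0.232), that of LHCB4.1 in 19 of the 24 omissions. Bacterial and phage control probe sets also had slopes at 78 h with the block, such as CreX-3 at -0.32 (adjusted p = 0.0366). All bioB, bioC, bioD and cre probe sets, called or not, had negative slopes there, from -0.15 (BioDn-5) to -0.63 (r2-Ec-bioB-M). Bacterial controls called as rising were dim, such as r2-Bs-lys-3 at 0.16 (adjusted p = 0.011, mean log2 4.79). Among 6 chlorophyll synthesis genes CHLI2, a subunit of magnesium chelatase, rose by 0.50 ± 0.08. Of 5 wall-loosening genes EXPA8 alone passed at either time without the block (2 fell at 6 h with it), with -1.50 ± 0.40 at 6 h (adjusted p up to 0.14 without 1 array). The list's median was -0.18 at 6 h (adjusted p = 0.424) and -0.05 at 78 h (adjusted p = 0.555). No list shift was called at 78 h for the Calvin cycle (median -0.10, adjusted p = 0.747), chlorophyll synthesis (-0.06, 0.877), heat shock proteins (-0.08, 0.555), alternative respiration (0.23, 0.508), gibberellin receptors (0.19, 0.859) or plastid ribosomal proteins (0.00, 0.926). With the block 1 gene each way passed in the Calvin cycle, in alternative respiration and in chlorophyll synthesis, and 1 heat shock gene fell. The 3 root markers had a median of -0.07 (adjusted p = 0.261). Of these PYK10, a beta-glucosidase abundant in roots, had a slope of -1.54 ± 0.21 (adjusted p = 0.000228). The root hair expansins EXPA7 and EXPA18 had slopes of 0.13 ± 0.09 and -0.07 ± 0.07.

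**Figure D2:**
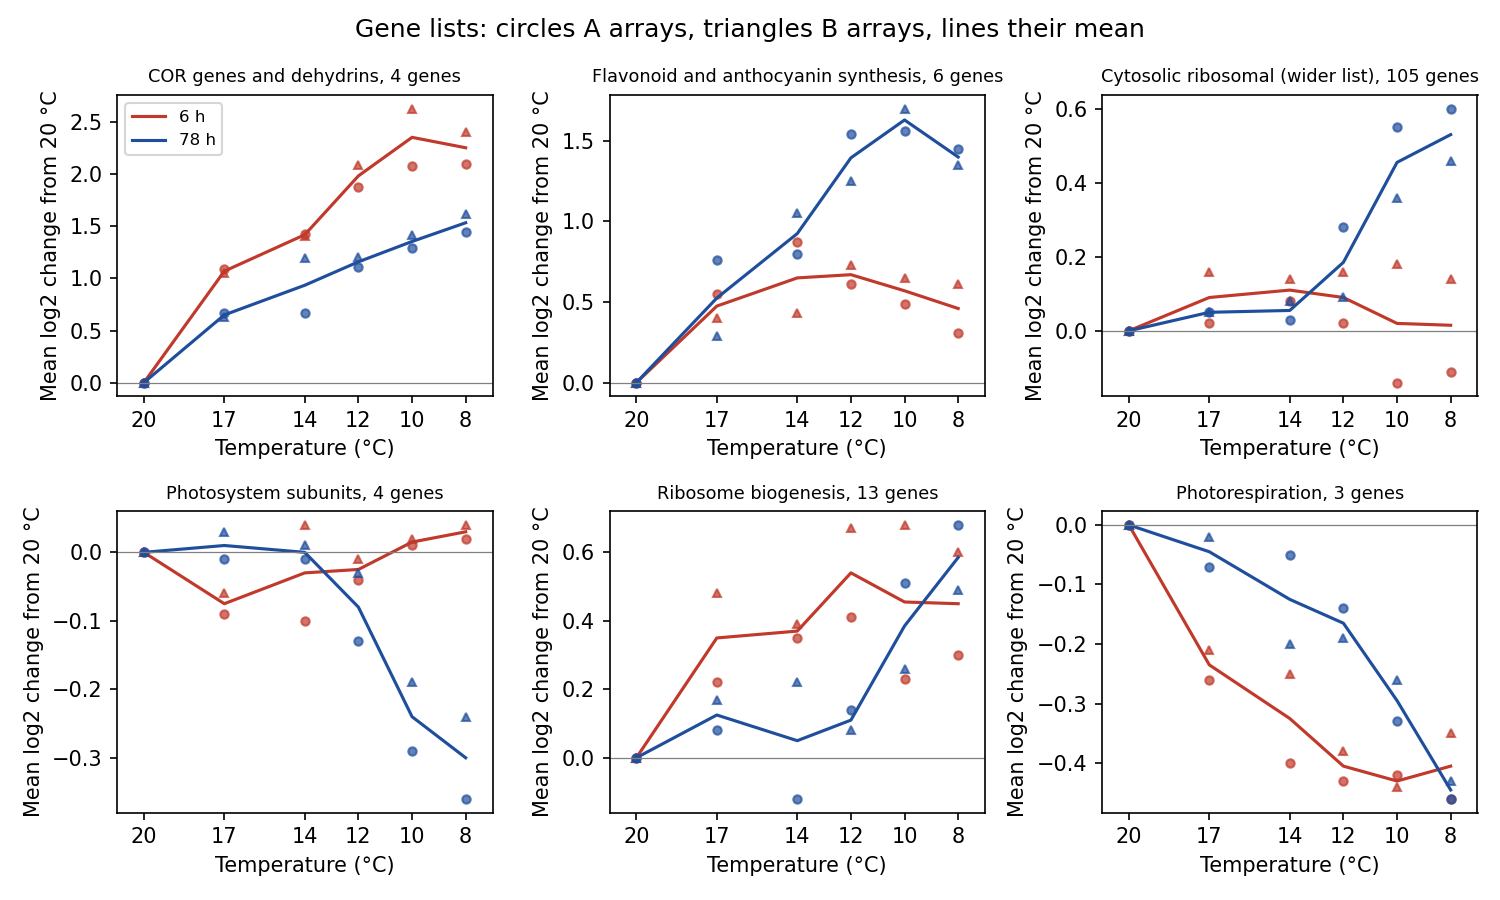
Mean log2 change from 20 °C (y axis) over the measured genes of 6 lists against temperature (x axis, from warm to cold) at 6 h (red) and 78 h (blue). Circles are A arrays, triangles B arrays, each set against the 20 °C array of the same letter and time, and lines are their mean. The cytosolic ribosomal panel shows the wider list of 105 genes, added after the annotation was seen. The median slope of the cold-regulated COR list was 1.63 at 6 h and 0.75 at 78 h, and that of the flavonoid list 0.10 and 1.47. By camera the difference between the times did not pass for the COR list (adjusted p = 0.319). It passed for the flavonoid list (adjusted p = 3.19e-05, but 0.121 with an estimated correlation).

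Lists with fewer than 3 measured members were not tested as lists. At 6 h the clock gene GI rose by 1.07 ± 0.27 and at 78 h had a slope of 0.33 ± 0.27, past the test only with the block, and TIC passed at neither time. The starch phosphorylating enzyme PWD and the disproportionating enzyme DPE1 fell at both times, PWD at -0.25 ± 0.05 at each and DPE1 at -0.48 ± 0.10 and -0.77 ± 0.10. In starch synthesis APL3, a large subunit of ADP-glucose pyrophosphorylase, had -0.34 ± 0.13 at 6 h, past the test only with the block, and rose by 0.96 ± 0.13 at 78 h. SBE2.2 passed at neither time. The sucrose phosphate synthase ATSPS4F fell at 6 h (-0.61 ± 0.15) and rose at 78 h (0.53 ± 0.15). The sucrose phosphatase AT2G35840 had -0.05 ± 0.08 and rose by 0.39 ± 0.08. The vacuolar invertase AT1G62660 had -0.49 ± 0.50 and -1.48 ± 0.50 and passed only at 78 h and only with the block. IAA29, AUR1, AGL24, JMT, LIL3:1, AT5G38710 and WRKY53 were the only members on named probe sets of the auxin, cell cycle, flowering, jasmonate, photoprotection, proline and salicylate lists. These genes passed at neither time, except for AGL24 at 6 h with the block (adjusted p = 0.00108). STZ was the only one of the 14 early cold regulators on a named probe set. Without at least 1 array the calls of GI at 6 h (adjusted p up to 0.1), PWD at both times (0.0842 and 0.0767), DPE1 at 6 h (0.0606), ATSPS4F at both (0.0887 and 0.258) and AT2G35840 at 78 h (0.0595) were lost. No member was named for 7 lists, among them abscisic acid, raffinose synthesis, fatty acid desaturation and nitrogen metabolism.

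Whether the response changed between 6 h and 78 h was tested as the difference of the slopes. DFR and UF3GT followed temperature at 78 h and had slopes of -0.04 and -0.02 at 6 h. The differences were 1.77 ± 0.27 (adjusted p = 0.00377) and 1.42 ± 0.29 (adjusted p = 0.0199). APL3 differed by 1.29 ± 0.18 and AT5G48490 by 2.00 ± 0.24. SECA2, a plastid protein translocase subunit, and the expansin-like gene EXLB1 went from falling at 6 h (-0.68 and -0.76) to rising at 78 h (0.84 and 0.49). AT1G80130 and SWEET13 rose at both times and more at 78 h, by 1.51 and 1.26. AT2G34620, AT2G03750, AT1G72030 and AT1G60590 fell at 6 h and had slopes higher by 1.46, 1.25, 1.21 and 1.2 at 78 h. In the other direction AT1G20030 had 2.12 at 6 h and 0.25 at 78 h (difference -1.87 ± 0.28, adjusted p = 0.00331). AT1G32860 had 2.82 and 1.05, AT3G59350 1.38 and -0.39, AT3G55760 1.65 and 0.21, AT2G27830 0.99 and -0.53, and EXLA1 1.01 and -0.47. AT4G09760, a choline kinase gene, rose at 6 h (0.96) and fell at 78 h (-0.77), and PYK10 had -0.06 and -1.54. STZ, at 2.31 and 0.04, and COR47, at 2.44 and 0.63, did not pass the test of the difference (adjusted p = 0.0861 and 0.312), though both passed with the block (0.0072 and 4.7e-05). The calls of UF3GT (adjusted p up to 0.0694), AT1G80130 (0.0558), SWEET13 (0.0928), AT2G03750 (0.147, lost in 17 omissions), AT1G32860 (0.0691), AT3G59350 (0.113), AT3G55760 (0.127), AT2G27830 (0.0604), EXLA1 (0.102) and PYK10 (0.0581) were each lost without at least 1 array.

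In all, 583 probe sets had a slope that differed between the times (321 higher and 262 lower at 78 h, but 304 and 307 with cyclic loess). Of these, 346 had slope estimates of opposite sign, whether or not either slope was called. Of the 583, 285 had no called slope at 6 h and 196 none at 78 h. With the letter as a block the slopes of 3354 probe sets differed (1789 higher and 1565 lower), and all 583 were among them. Leaving out 1 array gave between 238, without the A array of 20 °C at 78 h, and 852, without the B array of 8 °C at 6 h. Each of 9 arrays moved the number by over 1.5-fold. Those 9 were, with the number left, the A arrays of 20 °C (307), 10 °C (376) and 8 °C (248) and the B array of 20 °C (293) at 6 h. At 78 h they were the A arrays of 20 °C (238), 17 °C (374) and 8 °C (316) and the B arrays of 20 °C (368) and 8 °C (292). Slopes at the 2 times, which rest on separate control arrays, correlated at 0.52 across probe sets, which are not independent replicates. Of the probe sets rising at 6 h 395 also rose at 78 h, against 59.2 for independent lists, and of those falling 675 also fell, against 94.8. Of all, 49 of the 1119 called at both times went opposite ways. With the block, 1121 rose at both times against 400.8 and 1668 fell at both against 505.6.

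Among lists the difference was called for 4. Flavonoid genes had a median difference of 1.13 (adjusted p = 3.19e-05; adjusted p = 0.121 with an estimated correlation; 1.22 in A and 0.99 in B). There were 2 of 6 past the test and 4 of 6 adjusted over the list alone or with the block. Cytosolic ribosomal proteins had 0.41 (adjusted p = 3.04e-05; adjusted p = 0.121 with an estimated correlation; 0.57 in A, and 0.25 in B, where adjusted p = 0.0566). AT3G09200 was past the test and all 4 past it adjusted over the list alone or with the block. Photosystem subunits had -0.34 (adjusted p = 3.04e-05; adjusted p = 0.0225 with an estimated correlation; adjusted p = 0.0966 with both the block and an estimated correlation; -0.42 in A and -0.25 in B). PSAN and PSAE-1 were past the test and all 4 past it adjusted over the list alone or with the block. The bacterial and phage control probe sets of bioB, bioC, bioD and cre also all had negative slope differences. These ran from -0.09 (BioDn-5) to -0.60 (r2-Ec-bioB-M), and none was called with or without the block. Plastid ribosomal proteins had 0.15 (adjusted p = 0.0468; adjusted p = 0.397 with an estimated correlation; 0.13 in A, where adjusted p = 0.252, and 0.16 in B), with AT3G13120 past the test and 2 members with the block. The COR list, at -0.55, did not pass (adjusted p = 0.319, and 0.0504 with the block). Nor did ribosome biogenesis (0.08, 0.926), photorespiration (0.03, 0.818), the leucine breakdown genes (0.15, 0.889), gibberellin receptors (-0.33, 0.109), reactive oxygen scavenging (0.37, 0.0614), light-harvesting proteins (-0.21, 0.0783), chlorophyll synthesis (0.18, 0.223), heat shock proteins (-0.13, 0.232), the Calvin cycle (-0.14, 0.926), alternative respiration (0.00, 0.926), wall loosening (0.05, 0.952) or the root markers (-0.11, 0.182). Within lists not called, CHLI2 (0.52 ± 0.12), GR1 (0.68 ± 0.13), SAPX (0.82 ± 0.10) and LHCB4.2 (-0.78 ± 0.16) passed singly. With the block 3 chlorophyll synthesis genes had higher slopes at 78 h. Lower slopes at 78 h with the block had 2 COR genes, 2 light-harvesting genes and 1 gene each of the Calvin cycle, the gibberellin receptors, photorespiration and reactive oxygen scavenging, and leucine breakdown had 1 gene each way. Adjusted over the list alone, light-harvesting proteins had 2 members past the test, and gibberellin receptors, photorespiration, leucine breakdown and reactive oxygen scavenging each 1 with a lower slope at 78 h that did not pass over all probe sets. At 6 h the same adjustment added 1 light-harvesting gene, 1 heat shock gene and 2 genes of reactive oxygen scavenging, and at 78 h 1 Calvin cycle gene. Median, mean and camera's direction differed in sign in lists that were not called. These were chlorophyll synthesis at 78 h (median -0.06, mean 0.01), light-harvesting proteins (0.02 and -0.03) and root markers (-0.01 and -0.01, direction upward) at 6 h. For the difference they were photorespiration (0.03 and -0.02), wall loosening (0.05 and -0.07) and leucine breakdown (0.15 and 0.05, direction downward). The call of the plastid ribosomal difference was lost in 11 omissions of 1 array (adjusted p up to 0.196). At 6 h those of gibberellin receptors and sugar starvation were lost in 13 and 3 (up to 0.196 and 0.08).

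**Figure D3:**
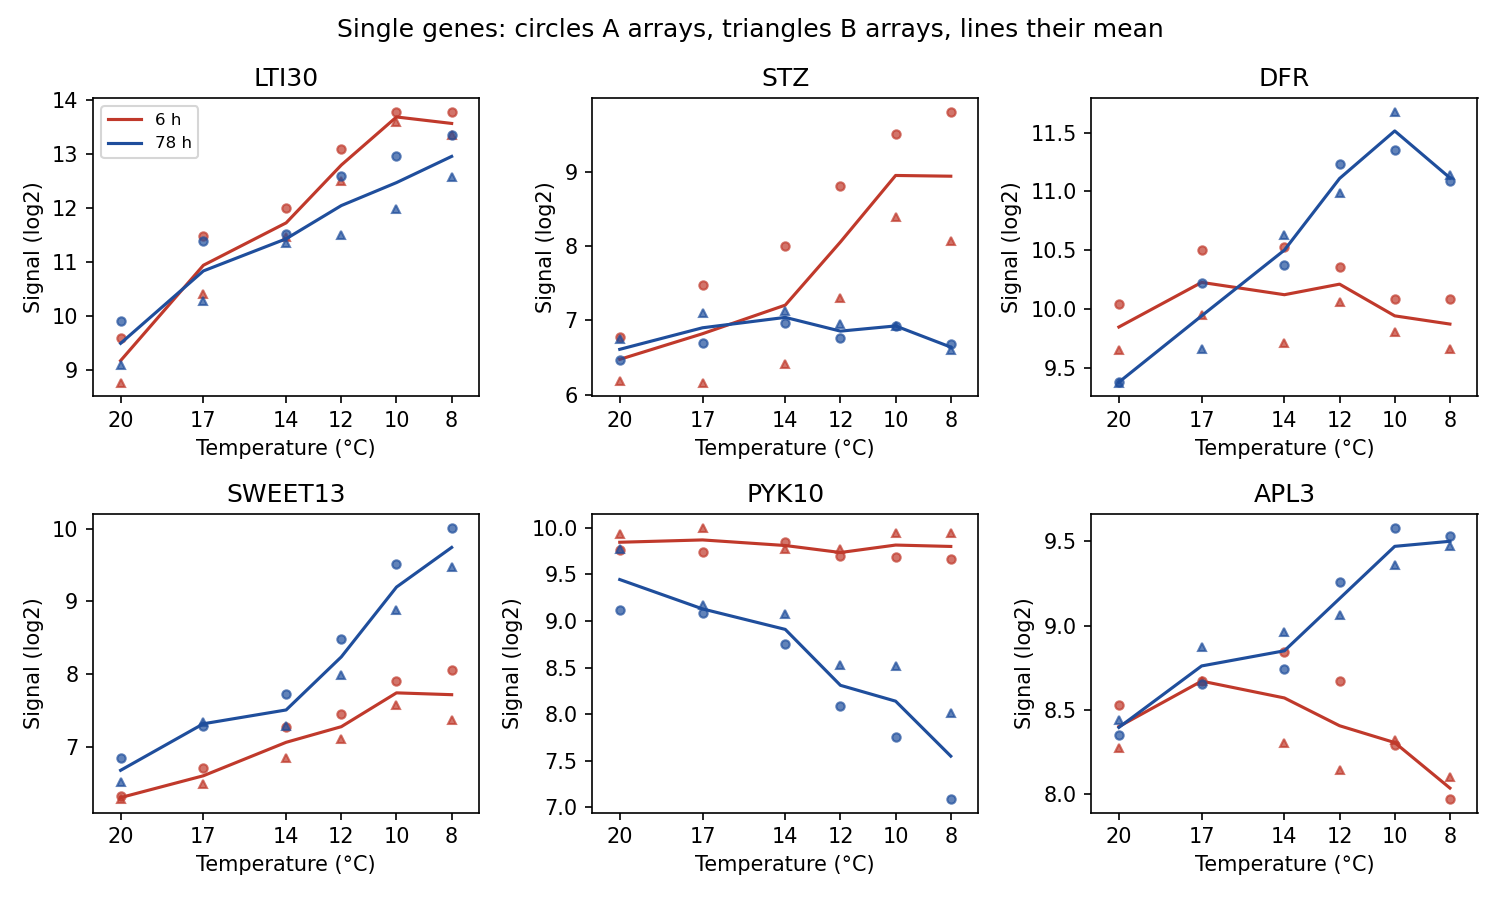
Signal in log2 (y axis) of 6 genes against temperature (x axis, from warm to cold) at 6 h (red) and 78 h (blue), with circles for A arrays, triangles for B arrays and lines for their mean. LTI30 rose at both times, the slopes of STZ were 2.31 and 0.04, and DFR, SWEET13, PYK10 and APL3 had slopes that differed between the times.

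Each temperature was also compared with 20 °C at the same time, to find the mildest cooling with a measurable response. After 6 h, LTI30 was 5.86-fold higher at 14 °C (2.55 ± 0.51 log2, adjusted p = 0.0499), 12.3-fold higher at 12 °C and 22.8-fold higher at 10 °C. At 8 °C it was higher by 4.39 ± 0.51 log2. AT2G34620 had changes of -1.34 ± 0.12, -2.08 ± 0.12, -2.73 ± 0.12 and -2.55 ± 0.12 at these temperatures. AT5G35970 (1.42 ± 0.28) and AT3G26510 (-1.15 ± 0.19) also passed at 14 °C. At 12 °C AT1G16850 rose by 2.01 and AT4G33666 fell by 1.84, and at 10 °C AT1G51090 rose by 3.38 and AT3G47560 fell by 2.12. After 78 h the strongest named genes at 14 °C were GR1 (0.93 ± 0.13), AT3G54400 (0.50 ± 0.08), DI19 (-0.68 ± 0.10) and PGRL1B (-0.76 ± 0.11), of cyclic electron transport. At 12 °C they were LTI30 (2.55 ± 0.51), DFR (1.74 ± 0.27), AT5G02230 (-1.41 ± 0.27) and AT3G24100 (-1.22 ± 0.24). At 10 °C LTI30 rose by 2.98 ± 0.51 and AT2G16890 by 2.61 ± 0.16, and AT3G56060 and EXPA8 had changes of -2.39 ± 0.53 and -2.31 ± 0.57. At 8 °C LTI30 was higher by 3.46 ± 0.51 log2 and SWEET13 8.41-fold higher, and AT3G56060 and EXPA8 had changes of -2.64 ± 0.53 and -2.53 ± 0.57.

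At 17 °C no probe set passed in limma at either time, with 834 at 6 h and 458 at 78 h at an unadjusted p under 0.05, and with the block 37 and 3 passed. The COR genes and dehydrins, not tested as a list at single temperatures, had mean changes at 17 °C of 1.09 in A and 1.05 in B at 6 h, and of 0.67 and 0.63 at 78 h. At 6 h the numbers were 89 at 14 °C, 619 at 12 °C, 1482 at 10 °C and 1372 at 8 °C, and 1038, 2757, 4442 and 4289 with the block. With the 6 h arrays fitted alone they were 2, 212, 729 and 581, and 876, 2801, 4588 and 4495 with the block. At 78 h, with all arrays in the fit, the numbers were 8, 176, 971 and 1675, and 255, 1313, 3821 and 5075 with the block. In fits without the block these counts depended on single arrays. At 14 °C the number lay between 5 (without the A array of 14 °C or the B array of 20 °C) and 145 (without the B array of 14 °C) at 6 h, where 16 of the 24 arrays moved it by over 1.5-fold. At 78 h it lay between 0 and 7, and 20 arrays did. Among the named genes at 14 °C, AT2G34620 alone kept its call without any 1 array. LTI30 at 14 °C lost its call in all 24 omissions. LTI30, AT5G35970 and AT3G26510 reached adjusted p of 0.469, 0.373 and 0.239. AT5G35970 lost its call in 20. GR1, AT3G54400, DI19 and PGRL1B lost theirs in 14, 22, 22 and 19 and reached 0.375, 0.375, 0.375 and 0.528. Without the 20 °C arrays of letter A and of letter B the numbers at 6 h were 306 and 221 at 12 °C, 910 and 693 at 10 °C and 835 and 556 at 8 °C. Without the A and the B array of the colder group itself they were 269 and 193 at 12 °C and 835 and 894 at 10 °C, and 606 without the A array of 8 °C. At 78 h, without the 20 °C arrays of A and of B, they were 38 and 30 at 12 °C, 366 and 508 at 10 °C and 721 and 1040 at 8 °C. Without the colder group's own array they were 19 and 50 at 12 °C, 409 and 494 at 10 °C and 661 and 969 at 8 °C. Named calls lost without 1 array were those of AT1G16850 at 12 °C (adjusted p up to 0.217) and AT1G51090 at 10 and 8 °C (0.0629 and 0.11) at 6 h. At 78 h they were those of LTI30 at 12 and 10 °C (0.39 and 0.0609), DFR (0.127), AT5G02230 (0.323) and AT3G24100 (0.332) at 12 °C, and at 10 and 8 °C those of AT3G56060 (0.181 and 0.0792) and EXPA8 (0.341 and 0.174). Curvature over temperature was called for 0 probe sets at 6 h (888 at an unadjusted p under 0.05, 1 with the block). It was called for 3 at 78 h (1241 unadjusted, 247 with the block). AT5G53920, named after its value was seen, was the only one with a single gene. Without 1 array the numbers lay between 0 and 3 at 6 h, with 3 without the B array of 8 °C at 6 h, and between 0 and 7 at 78 h, where 20 of the 24 arrays moved it. Between the 20 °C plants of 78 h and of 6 h no probe set was called in limma (0 past the test, 325 at an unadjusted p under 0.05, and 0 and 1736 with the block). With 2 arrays on each side this does not show that they were alike.

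**Figure D4:**
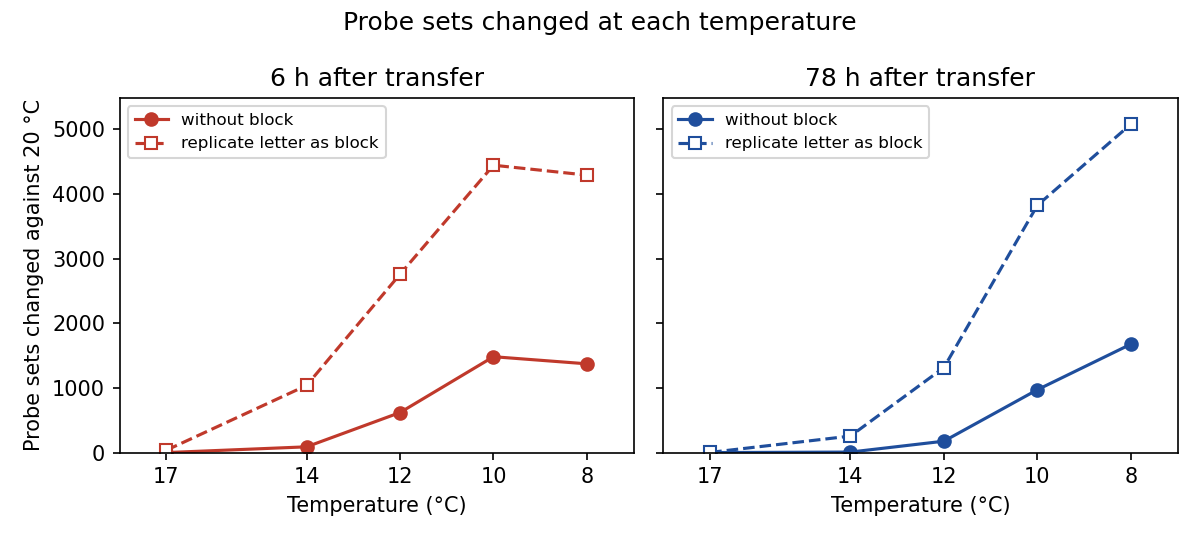
Number of probe sets changed against 20 °C (y axis) at each lower temperature (x axis, from warm to cold) after 6 h (left) and 78 h (right), for limma without a block (filled circles) and with the replicate letter as a block (open squares). Without the block the numbers at 8 °C were 1372 and 1675, and at 17 °C both were 0.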

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

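The counts over other assignments of the labels, and the tests of the 20 °C level and of a signal ceiling, were chosen after the results were seen, and so were the fits of each letter alone. The real labels gave 2513 probe sets with a slope at 6 h, and 1 of 100 assignments, the real one, gave as many (highest other 804). At 78 h it was again 1 of 100, with 2750 against 173. For the difference of the slopes 3 of 100 gave 583 or more. The other 2, with 689 and 643, exchanged the times of 4 and 3 of the 12 pairs, all at 14 to 20 °C. Within a group of 2 arrays neither can be told to lie apart. The dependence of counts on single arrays was measured by leaving each out without the block, so it includes the difference between the letters.

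Arrays of letter A and letter B differed at 13686 probe sets, 60.2% of those tested. RNA degradation or labelling length was argued against only as a shift shared by all groups, as the 3′ minus 5′ signal of actin, GAPDH and ubiquitin controls differed by 0.01 on average between A and B (SD 0.10, higher in A in 6 groups and lower in 6). Opposite shifts at the 2 times stay open, since actin alone was higher in A in all 78 h groups (1.36 against 0.94 at 20 °C). After cyclic loess 13097 probe sets still differed. The deposited arrays already had nearly the same distribution of values, which may have left loess little to remove. This count therefore does not decide on intensity-dependent scaling. Separate plantings, harvests or processing days stay open, as the labels do not say what the letters stand for, and no biological explanation was tested.

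Cytosolic ribosomal protein genes had higher slopes at 78 h than at 6 h, by a median of 0.48 over 105 genes, positive in 104. That bright probe sets shift together was argued against, as the highest median of 10000 random lists matched on signal was 0.15. The median was 0.41 after cyclic loess, a limited test of scaling on values already normalized between arrays. The lower of the letters' medians was 0.29 (0.69 in A), which argued against a single letter as the source. With a correlation estimated from the data the list's adjusted p was 0.53. As a hypothesis, longer cooling may raise these transcripts together, which stays untested on other samples.

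Over 16 cold-induced genes the median slope difference between 78 h and 6 h was -0.93, and the median response at 8 °C went from 1.85 to 0.88. COR15A had a difference of 0.11, the 4 COR genes and dehydrins were not called as a list (-0.55, adjusted p = 0.319), and of the 12 further genes 2 passed singly and the list had an adjusted p of 5.22e-07, or 0.525 with an estimated correlation. A higher level in the 20 °C plants at 78 h was argued against as the main source, as its median of 0.07 was 8.1% of the fall, though the level was higher in 14 of the 16 (quartiles 0.04 and 0.34), so a small part may come from it. The median level at 8 °C differed by -0.75, lower in 14 of the 16, which a signal ceiling alone would not give. For each gene this follows by arithmetic from its fall and its 20 °C difference, so it is not a separate argument. A median over the 16 does not settle it for COR15A and COR15B, whose signals were near the top of the range. A single letter was argued against by medians of -1.12 in A and -0.60 in B. As a hypothesis, the response of part of these genes may decline over 3 days.

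The remaining results stood out because limma's test of the slope difference between 78 h and 6 h passed. Higher at 78 h were AT5G48490 (2.00), DFR (1.77), SECA2 (1.52), AT1G80130 (1.51), AT2G34620 (1.46), UF3GT (1.42), APL3 (1.29), SWEET13 (1.26), EXLB1 (1.26), AT2G03750 (1.25), AT1G72030 (1.21), AT1G60590 (1.2), ATSPS4F (1.14), AT3G47560 (1.09), SAPX (0.82), GR1 (0.68), AT3G09200 (0.56), CHLI2 (0.52) and AT3G13120 (0.28). Lower were AT1G20030 (-1.87), AT1G32860 (-1.77), AT3G59350 (-1.77), AT4G09760 (-1.73), AT2G27830 (-1.51), PYK10 (-1.48), EXLA1 (-1.47), AT3G55760 (-1.44), AT2G32160 (-1.33), DI19 (-1.23), AT3G24100 (-1.10), LHCB4.2 (-0.78), PGRL1B (-0.69), PSAN (-0.43), AT3G54400 (-0.41) and PSAE-1 (-0.31). By camera, median differences stood out for flavonoid synthesis (1.13), cytosolic ribosomal proteins (0.41), plastid ribosomal proteins (0.15), photosystem subunits (-0.34), the wider ribosomal list (0.48), further cold-induced genes (-0.93), mitochondrial respiratory complexes (0.16), tubulins (-0.32) and UDP-glycosyltransferases (-0.06). With an estimated correlation all of these but photosystem subunits were lost (adjusted p = 0.121, 0.121, 0.397, 0.53, 0.525, 0.496, 0.358 and 0.78 in this order), and photosystem subunits were lost when the block was added (adjusted p = 0.0966). The 64 control probe sets were left out of the tests of slopes and temperatures above. Among them slopes at 78 h were called for GAPDH (0.30 and 0.41) and ubiquitin (-0.16, -0.18, -0.21, -0.22 and -0.27). With the block 20 of the 64 were called at 78 h against 7 without it, and 0 at 6 h in either fit. They included actin (-0.35, adjusted p = 0.000105) and bacterial and phage controls (CreX-3 -0.32, 0.0366, P1-cre-3 -0.23, 0.017, and bioD-5 -0.27, 0.0443). All bioB, bioC, bioD and cre probe sets, called or not, had negative slopes at 78 h, from -0.15 (BioDn-5) to -0.63 (r2-Ec-bioB-M). At 6 h their slopes lay between -0.10 (r2-Ec-bioC-3) and 0.06 (BioB-5). Bacterial controls called as rising at 78 h were r2-Bs-lys-3 (0.16, 0.011), TrpnX-5 (0.12, 0.0366) and ThrX-3 (0.10, 0.0369). These were dim, with mean log2 of 4.79, 4.66 and 5.02. The cause was not tested.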

How the results depend on the processing

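The A arrays alone, the B arrays alone, the block with each harvest time alone and the block with an estimated correlation were chosen after the data were seen. Each letter alone was fitted as a straight line on temperature, with scatter around the line as the error. Its counts and adjusted p-values are therefore not directly comparable with those of the main fit. Groups of 2 arrays limit all counts, and where an array was left out the remaining 1 was assumed to vary like the other groups. These omissions were fitted without the block, so the mean of that group also took up the letter difference. Calls lost in them therefore do not separate a single deviating array from the letter. Offsets before the logarithm were not run, because the values were already log. Of 141 called results on named genes, 0 were lost with the replicate block, 85 held without any 1 array, 56 were lost without at least 1 and 0 reversed. Calls on named genes were also lost with each harvest time alone (19), B arrays alone (11), cyclic loess (9), A arrays alone (7), trend and robust estimation (7), array weights (6), median centring (5), the dimmest 25% left out (4) and regression (1). Averaging the probe sets of a gene changed no list call. With each array centred on its median or with cyclic loess, the median change over all probe sets was at most 0.065 in any comparison. With centring, 1356 probe sets rose and 1292 fell at 78 h, and with loess 1282 rose and 1242 fell at 6 h, so for the slopes neither direction prevailed under every scaling. Falls outnumbered rises under the deposited scaling and both others at 10 and 8 °C and 78 h and at 14 and 12 °C and 6 h, but with the replicate block rises outnumbered falls at 10 °C and 78 h (2036 and 1785) and at 14 °C and 6 h (575 and 463). The cause of the changes was not tested.

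With the replicate block the counts were 6131 and 6711 for the slopes at 6 and 78 h, 3354 for their difference and 247 for curvature at 78 h. From 17 to 8 °C they were 37, 1038, 2757, 4442 and 4289 at 6 h, and 3, 255, 1313, 3821 and 5075 at 78 h. Plastid ribosomal proteins at 6 h became called (-0.168, adjusted p = 0.0401; adjusted p = 0.342 with an estimated correlation as well), and the block changed no other call of a list fixed beforehand. With the block and each time alone the counts were 6292 and 7908 for the slopes, 954 for curvature at 78 h, 34, 876, 2801, 4588 and 4495 from 17 to 8 °C at 6 h, and 11, 636, 2235, 5128 and 6509 at 78 h. Calls were then lost for photorespiration (-0.393, 0.055) and sugar starvation (-0.49, 0.055) at 6 h, and for reactive oxygen scavenging (0.569, 0.055) and sugar starvation (-0.403, 0.0522) at 78 h.

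In the A arrays alone the counts were 3872, 5189 and, for the difference, 2676. Calls were lost for photorespiration at 6 h (-0.397, 0.0883) and 78 h (-0.491, 0.0921), for ribosome biogenesis (0.211, 0.0883) and sugar starvation (-0.507, 0.0851) at 6 h and for the plastid ribosomal difference (0.135, 0.252), and the ribosome biogenesis difference was called (0.282, 0.0279). In the B arrays alone the counts were 4309 at 6 h and 962 for the difference. Flavonoid genes at 6 h (0.322, 0.0474) and the heat shock difference (-0.0459, 0.0474) were called, sugar starvation at 78 h (-0.309, 0.111) and the cytosolic ribosomal difference (0.25, 0.0566) were lost, and the wider ribosomal list at 6 h reversed to 0.0734 (adjusted p = 0.0162).

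With an estimated correlation, calls were lost at 6 h for COR genes (1.63, adjusted p = 0.106), gibberellin (0.268, 0.207), photorespiration (-0.393, 0.106), ribosome biogenesis (0.388, 0.392) and sugar starvation (-0.49, 0.122). At 78 h they were lost for COR genes (0.751, 0.158), cytosolic ribosomal proteins (0.444, 0.142), flavonoids (1.47, 0.106), photorespiration (-0.413, 0.106), reactive oxygen scavenging (0.569, 0.106), ribosome biogenesis (0.494, 0.359) and sugar starvation (-0.403, 0.106). For the difference they were lost for cytosolic ribosomal proteins (0.406, 0.121), flavonoids (1.13, 0.121) and plastid ribosomal proteins (0.149, 0.397). With the block as well, the same lists and medians lost their calls (adjusted p from 0.164 to 0.39), as did photosystem subunits at 78 h (-0.316, 0.135) and in the difference (-0.336, 0.0966).

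Array weights gave 54 for curvature at 78 h, 29 at 14 °C and 6 h, and 38, 532 and 2644 at 14, 12 and 8 °C and 78 h. Cyclic loess gave 1 for curvature and 1 at 14 °C at 78 h, and lost gibberellin (0.264, 0.0582) and sugar starvation (-0.436, 0.0592) at 6 h and the plastid ribosomal difference (0.0571, 0.221). Leaving out the dimmest 25% gave 1 for curvature and 3 at 14 °C at 78 h, and lost gibberellin (0.268, 0.0696), sugar starvation at 6 h (-0.49, 0.0831) and 78 h (-0.403, 0.05) and the plastid ribosomal difference (0.149, 0.0924). Trend and robust estimation gave 1 for curvature at 78 h, 42 at 14 °C and 6 h and 3 at 14 °C and 78 h. Median centring gave 13 for curvature and 4 at 14 °C at 78 h, with the plastid ribosomal difference at 0.18 (0.0711). Each time alone gave 1458 slopes at 6 h, 2, 212, 729 and 581 from 14 to 8 °C at 6 h and 1 at 14 °C and 78 h, and lost gibberellin (0.268, 0.0528) and sugar starvation (-0.49, 0.0528) at 6 h. Regression on temperature gave 882 differences and lost the plastid ribosomal one (0.149, 0.063).

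Without 1 array, counts ranged from 1473 to 2554 (slope at 6 h), 1460 to 2808 (78 h), 238 to 852 (difference), 0 to 3 (curvature at 6 h) and 0 to 7 (78 h). At 6 h they ranged from 0 to 2 at 17 °C, 5 to 145 at 14 °C, 193 to 670 at 12 °C, 693 to 1554 at 10 °C and 556 to 1423 at 8 °C. At 78 h the ranges were 0 to 7 at 14 °C, 19 to 201 at 12 °C, 366 to 1013 at 10 °C and 661 to 1757 at 8 °C. Medians of lists that kept their call moved by over 1.5-fold for ribosome biogenesis (0.175 to 0.429) and photorespiration (-0.504 to -0.257) at 6 h. List medians whose call moved ranged at 6 h from -0.0374 to 0.288 (flavonoid), 0.234 to 0.357 (gibberellin), -0.255 to -0.0811 (plastid ribosomal) and -0.616 to -0.358 (sugar starvation), and at 78 h from -0.244 to -0.138 (light-harvesting). For the difference they ranged from -0.262 to -0.155 (light-harvesting), -0.153 to -0.0677 (root markers), 0.0625 to 0.236 (plastid ribosomal) and 0.267 to 0.463 (reactive oxygen).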

Other observations

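The gene lists in this part were chosen after the annotation table was seen and before any of their values was tested, and the fits of each letter alone were chosen after the data were seen. A wider list of 105 cytosolic ribosomal protein genes rose with cooling at 78 h, where 45 members passed in limma (73 adjusted over the list alone, 96 with the block), with a median slope of 0.47 (camera adjusted p = 4.03e-24; adjusted p = 0.538 with an estimated correlation; 0.56 in A and 0.39 in B). At 6 h the median was -0.03 with 1 member past the test, or 3 rising and 3 falling with the block (adjusted p = 0.804; -0.13 in A, adjusted p = 0.00206, and 0.07 in B, adjusted p = 0.0162, so that the letters had opposite signs). The slopes differed between the times by a median of 0.48 (adjusted p = 4.82e-26; adjusted p = 0.53 with an estimated correlation; 0.69 in A and 0.29 in B), with 8 members past the test, 28 adjusted over the list alone and 86 with the block, among them AT3G06700 (0.87 ± 0.15). Further cold-induced genes, 12 measured, rose at 6 h in 9 cases (11 adjusted over the list alone or with the block), with a median of 1.62 (adjusted p = 1.41e-12; adjusted p = 0.406 with an estimated correlation; 2.11 in A and 1.32 in B). At 78 h 6 rose (7 adjusted over the list alone, 8 with the block), with a median of 0.60 (adjusted p = 0.00211; adjusted p = 0.78 with an estimated correlation; 0.50 in A and 0.49 in B). COR27 and AT5G43260 had lower slopes at 78 h than at 6 h, by -1.06 and -0.85, 2 of 12 in the difference (7 adjusted over the list alone, 9 with the block).

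Subunits of the CCT chaperonin, which folds actin and tubulin, rose at 78 h in 4 of 8 cases (5 adjusted over the list alone or with the block), AT1G24510 most, by 0.53 ± 0.10 (list median 0.36, adjusted p = 0.00242; adjusted p = 0.496 with an estimated correlation; 0.36 in A and 0.30 in B). At 6 h the median was 0.22 with 0 past the test in limma, 2 adjusted over the list alone and 4 with the block (adjusted p = 0.0437; adjusted p = 0.717 with an estimated correlation; 0.03 in A, adjusted p = 0.851, and 0.43 in B, adjusted p = 7.66e-05). Of 7 tubulins TUB1, TUB6 and TUA6 fell at 78 h, at -0.50, -0.47 and -0.44 (median -0.12, adjusted p = 0.0188, and 0.0507 with the block; adjusted p = 0.496 with an estimated correlation). The tubulin slopes were lower at 78 h by a median of -0.32 (adjusted p = 0.000216; adjusted p = 0.358 with an estimated correlation; -0.34 in A and -0.26 in B), with 1 past the test, 4 adjusted over the list alone and 3 with the block. Of 10 RNA polymerase subunits NRPB9B and NRPB7 rose at 78 h, by 0.79 ± 0.10 and 0.41 ± 0.07 (median 0.23, adjusted p = 0.0161; adjusted p = 0.78 with an estimated correlation; 0.39 in A and 0.14 in B; 4 rose with the block). Of 47 UDP-glycosyltransferase genes with a UGT symbol 8 rose and 3 fell at 6 h (11 and 4 with the block), UGT78D3 most within this list, by 1.63 ± 0.14 (median 0.06, adjusted p = 0.0188; adjusted p = 0.717 with an estimated correlation; 0.07 in A and 0.08 in B). Their median slope difference was -0.06 (adjusted p = 0.0487; adjusted p = 0.78 with an estimated correlation; -0.02 in A and -0.09 in B), with 1 higher and 2 lower at 78 h (2 and 7 with the block). Nuclear genes of mitochondrial respiratory complexes, 21 measured, differed between the times by a median of 0.16 (adjusted p = 0.00128; adjusted p = 0.496 with an estimated correlation; 0.23 in A and 0.11 in B), with 0 members past the test in limma and 7 with the block. Plastid-encoded photosystem, cytochrome and ATP synthase genes, 33 measured, had a median of -0.31 at 78 h (adjusted p = 0.0641, and 0.011 with the block; adjusted p = 0.936 with both the block and an estimated correlation), with 0.04 in A (adjusted p = 0.819) and -0.62 in B (adjusted p = 4.04e-12), and 1 rose and 1 fell without and 1 rose and 8 fell with the block. No list shift was called in any comparison for core histones, expansins, the XTH family, SWEET transporters, mitochondrion-encoded genes, plastid-encoded NDH and ribosomal genes, or RNA editing factors, though single members passed, as 3 rising and 3 falling expansins did at 6 h. SAUR genes and elongation factors had too few members. Beside CCT at 6 h and plastid-encoded photosystem genes at 78 h, both called in B only, some lists were called in 1 letter only. In A these were the respiratory complexes at 6 h (-0.15, adjusted p = 0.00206), plastid-encoded ribosomal proteins at 78 h (0.15, 0.0057), and the differences of CCT (0.34, 0.00618) and RNA polymerase subunits (0.32, 0.00473). In B these were mitochondrion-encoded genes (-0.16, 0.0357), plastid-encoded NDH (-0.25, 0.0246) and plastid-encoded photosystem genes (-0.10, 0.0313) at 6 h, respiratory complexes (0.12, 0.04) and NDH (-0.36, 0.0072) at 78 h, and the differences of plastid-encoded ribosomal proteins (0.29, 0.0465), plastid-encoded photosystem genes (-0.21, 6.91e-05) and UDP-glycosyltransferases (-0.09, 0.00338). Tubulins at 78 h were called in A (-0.28, 0.00883) and not in B (-0.09, 0.274). Several calls of these lists near the threshold were not stable. Without 1 array, that of the UDP-glycosyltransferase difference was lost in 14 of the 24 omissions (adjusted p up to 0.163) and also with cyclic loess (0.0694) and the dimmest 25% left out (0.102). CCT at 6 h was lost in 7 omissions (up to 0.468), with centring (0.0504) and with the dimmest 25% left out (0.0605). UDP-glycosyltransferases at 6 h were lost in 2 omissions (up to 0.0831) and with the dimmest 25% left out (0.0605), and RNA polymerase subunits at 78 h in 1 (0.0754). Tubulins at 78 h were lost in 1 omission (0.0582), with the dimmest 25% left out (0.0605) and with each time alone (0.0936, and 0.114 with the block).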
